A study of Mus musculus with 24 samples.

How the data were processed

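Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in macrophages grown from the bone marrow of male mice. The cells were wild type (WT) or carried floxed copies of the gene for GRIP1 (KO), and both genotypes carried LysM-Cre, a recombinase made in myeloid cells. GRIP1 is a p160 coactivator of nuclear receptors and is encoded by Ncoa2. Each genotype received vehicle, 100 nM dexamethasone (Dex, a synthetic glucocorticoid) or 10 ng/ml interleukin 4 (IL4), and each of the 6 groups has 4 libraries, 24 in all. The titles give 24 hours for every group, while the treatment label of the vehicle libraries says 25 hours. Groups and replicate numbers were taken from the titles. The labels do not say whether the libraries of a group came from separate mice or cultures, so the p-values measure only the spread between libraries.

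The authors deposited a table of read counts per peak and library for 144411 peaks, with the peak's position, its length in bases and a true or false mark. A further deposited table holds the authors' log2 fold changes and the authors' p-values, unadjusted and adjusted, for 9 comparisons of 71942 peaks, with the nearest gene and the signed distance to its transcription start site (TSS). The mark is true for 72540 peaks, among them the 71942 of the second table, and for none of the 13379 peaks of 1 kb or more. How the mark was set is not given in the sources used here. The submitters' processing notes name fastp, Bowtie2, SAMtools, MACS2, featureCounts and edgeR without their roles, and the mm10 build. The counts are whole numbers without normalisation. The deposited log2 fold changes were used only as a check of scale: against those computed here their slope was 1.00 in each of the 9 comparisons, so both are in base 2. Peaks range from 121 to 16969 bases, with a median of 392.

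A peak that the second table leaves out was given the nearest TSS listed there within 50000 bases, unless an end of a gene missing from that table lay nearer. The deposited distances run from the middle of the peak along the strand of the gene: 100.0% of them equal that distance within 5 bases. In all, 47525 peaks got a gene in this way and 24944 peaks kept none. The nearest TSS does not show which gene a peak regulates.

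Counts were analysed in R 4.3.3 with edgeR 4.0.16. Peaks with low counts were removed by filterByExpr, which left 130103 tested peaks and removed 14308. Libraries were scaled by TMM factors, which ran from 0.935 to 1.07. One quasi-likelihood model with robust estimation and a mean per group was fitted to the 24 libraries, and each comparison was an F test. P-values were adjusted by the Benjamini-Hochberg method over the tested peaks, and a peak was called at an adjusted p below 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of F. Levels are TMM-scaled CPM, given as mean ± SD of the 4 libraries. The median tested peak held 33 counts per library.

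The comparisons were Dex and IL4 against vehicle in each genotype, IL4 against Dex in WT, KO against WT under each treatment, and the difference between genotypes in the Dex and in the IL4 effect (the interactions). The tests were tried on simulated data, in which known changes were added to few peaks. For WT Dex these were 67 peaks at 1.5-fold, 67 at 2-fold and 66 at 3-fold among 127633 tested. Adjustment is stricter when few peaks change. The shares for WT Dex are therefore likely too low for the real comparison, which called 21655 peaks. In the comparison of WT Dex with vehicle, 32.8% of peaks changed 1.5-fold were called, 65.7% at 2-fold and 87.9% at 3-fold, with 6 of the unchanged peaks called. In the Dex interaction the shares were 10.4%, 32.8% and 74.2%, with 8 unchanged peaks called.

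Before the data were examined, 19 gene lists with 389 entries were fixed, of which 348 entries had an assigned peak. They cover glucocorticoid receptor targets, IL4 and STAT6 targets, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, antigen presentation and costimulation, efferocytosis and scavenger receptors, lipid and fatty acid metabolism, tissue repair and matrix, macrophage lineage genes, the KLF family, p160 coactivators and corepressors, the cell cycle, and markers of 7 other kinds of cell. Each list was tested against the other tested peaks with camera of limma 3.58.1 on log2 CPM (prior count 2), at a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the 19 lists of a comparison. Calls were also counted with p-values adjusted over the list alone. Some genes stand on more than 1 list, so results of different lists are not separate. Mertk and Cd163, for example, are also among the glucocorticoid receptor targets, as is Klf9 of the KLF family. The fry test, which does not compare a list with other peaks, was an alternative. In simulated data camera picked out a list of 100 peaks shifted 1.2-fold, and gave p below 0.05 for 0 of 50 unshifted lists. The peaks were simulated independently and the list was shifted in the same direction throughout. Peaks of a real list can be correlated and move both ways, which this trial does not cover.

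Genes named in the text follow a rule fixed at the same time. For Dex and for IL4 in WT it takes the 6 largest rises and the 4 largest falls among called peaks of above-median abundance whose treated and vehicle CPM do not overlap, with at most 1 peak per gene. It adds up to 2 genes per list with the smallest p (1 for the macrophage lineage, KLF, coactivator and cell cycle lists, none for the marker lists), up to 5 peaks in each direction with the smallest p for genotype, interactions and both treatments together, and Ncoa2.

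Called peaks within 1000 bases of a TSS were compared with the other tested peaks by a two-sided Fisher's exact test over 110959 tested peaks with a TSS; neighbouring peaks are not independent. Peaks called between genotypes were counted in 5 Mb windows, and a window was called dense if it held at least 5 such peaks at a rate at least 5 times that of all tested peaks. The calls were shuffled over the tested peaks 1000 times. Peaks called for both treatments were compared with the overlap of independent lists, with 100 simulated data sets in which no group differed but the vehicle libraries were shared, and with the vehicle libraries split between the comparisons.

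Alternatives were DESeq2 1.42.0, DESeq2 size factors, total counts and loess offsets as scaling, no low-count filter or a filter of 1 CPM in 4 libraries, only peaks with the authors' mark, only the groups compared, a block for the replicate number, stricter thresholds, each library left out in turn, and a fit without the 3 WT libraries numbered 1. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Motif enrichment was also planned then, but needs a genome sequence and was not run.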

Results

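The experiment asked how a glucocorticoid and IL4 change open chromatin in macrophages, and what the coactivator GRIP1 contributes. Accessibility was read as the count of ATAC-seq reads in each peak, in 6 groups of 4 libraries. WT vehicle libraries 1 to 4 held 13224169, 9119982, 9628590 and 9700276 counts in peaks. WT Dex libraries held 15042768, 5820149, 13081998 and 21939330, and WT IL4 libraries 11841642, 16625875, 9633134 and 10422319. KO vehicle libraries held 7876894, 14089351, 7552327 and 11025620. KO Dex libraries held 9970100, 14910136, 13288578 and 17845255, and KO IL4 libraries 9863997, 12975023, 10838511 and 12507810. Over the 130103 tested peaks the first principal component held 40.2% of the variance and set the IL4 libraries apart. The second held 11.2% and set vehicle apart from both Dex and IL4, with the IL4 libraries between vehicle and most Dex libraries. The third held 6.36% and set KO apart from WT. The fourth held 4.07% and set WT Dex replicate 2 (-127) apart from the other libraries (-26.4 to 44.6). That library had the lowest total and the largest share of peaks with no count, 2.57%.

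**Figure D1:**
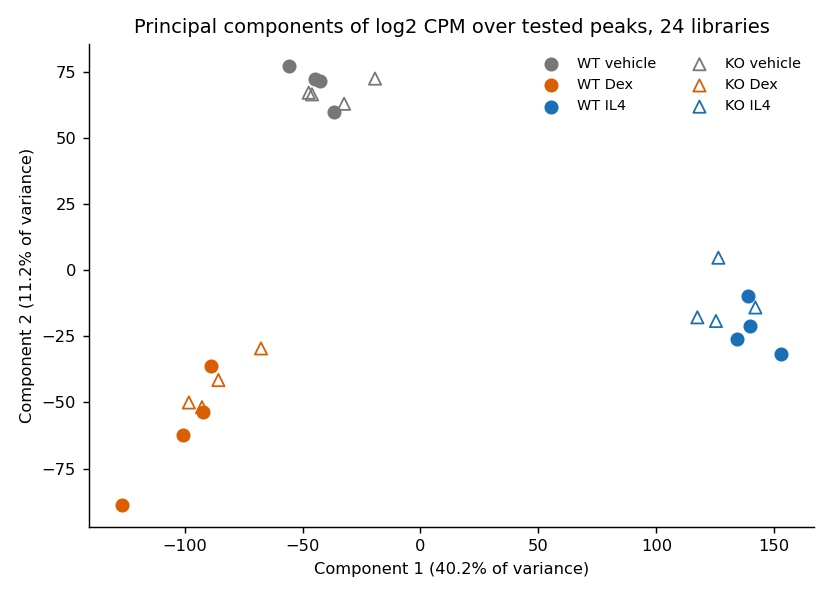
Each point is 1 of 24 libraries, placed by the first and the second principal component of log2 CPM over 130103 tested peaks; colour gives the treatment and marker shape the genotype. The first component, with 40.2% of the variance, separates IL4 from the other libraries, and the second, with 11.2%, separates vehicle from both Dex and IL4.

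The effect of Dex was asked by comparing the 4 WT Dex libraries with the 4 WT vehicle libraries. A peak inside Zbtb16, which encodes a zinc finger transcription factor, at chromosome 9, 48723286 to 48724099, rose from 1.24 ± 0.72 to 27.5 ± 4.6 CPM (SD, n = 4), a log2 fold change of 4.42 ± 0.17 (SE). Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor, rose at a peak 1.4 kb from its TSS (chromosome 17, 28515844 to 28516378) from 4.36 ± 0.74 to 58.2 ± 6.9 CPM, and at a neighbouring peak by a log2 fold change of 3.51 ± 0.11. Klf9, a transcription factor gene, rose at chromosome 19, 23134036 to 23136231 from 31.8 ± 4.3 to 168 ± 12 CPM. Accessibility fell at a peak inside Prkcb, which encodes protein kinase C beta, 39.1 kb from its TSS, from 11.5 ± 4.9 to 2.18 ± 1.4 CPM. The other largest rises lay at peaks assigned to Hs6st1 (4.28 ± 0.23, SE), Dock10 (4.27 ± 0.38), Ppp1r21 (3.80 ± 0.21) and Cyp7a1 (3.71 ± 0.23), the last of these the gene for the rate-limiting enzyme of bile acid synthesis. The other largest falls lay near Rapgef5 (-2.56 ± 0.37), Nap1l2 (-2.40 ± 0.18) and Tlk1 (-2.35 ± 0.26).

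Among 376 tested peaks of 30 glucocorticoid receptor targets, 120 rose and 24 fell with Dex, and 173 were called when adjusted over the list alone. Their mean log2 fold change was 0.32, and the list stood above the other peaks (camera, adjusted p = 7.88e-10; adjusted p = 0.000286 with an estimated correlation, and from 9.42e-12 to 0.00280 over its camera alternatives). Efferocytosis and scavenger receptors had 66 peaks that rose and 25 that fell among 355, with 111 called when adjusted over the list alone. Mertk, a receptor for the uptake of dying cells, rose by 1.37 ± 0.08 at a peak inside the gene, and Cd163, the haemoglobin scavenger receptor, by 2.66 ± 0.20 at a peak 25.3 kb away. Both genes also belong to the glucocorticoid receptor targets. The efferocytosis list was higher at adjusted p = 0.0150, but adjusted p = 0.0795 with an estimated correlation (0.000207 to 0.0826 over its camera alternatives). The KLF family had 45 peaks that rose and 14 that fell among 227 (76 adjusted over the list alone), with adjusted p = 0.0150, but adjusted p = 0.103 with an estimated correlation (0.000207 to 0.167). Tissue repair and matrix genes moved the other way, with 20 peaks that rose and 46 that fell among 271 (76 adjusted over the list alone), at adjusted p = 0.0150, but adjusted p = 0.0795 with an estimated correlation (0.0108 to 0.112). In that list a peak near Pdgfb, a growth factor gene, had a log2 fold change of -0.81 ± 0.09, and 1 near Spp1, the osteopontin gene, 0.95 ± 0.12.

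The other lists did not pass in the reported fit. IL4 and STAT6 targets had 59 peaks that rose and 31 that fell among 400 (103 adjusted over the list alone; adjusted p = 0.420), with rises near Chil3, which encodes the lectin Ym1 (2.74 ± 0.14), and Slc7a2, an arginine transporter gene (1.34 ± 0.12). Inflammatory cytokines and NF-kB targets had 35 that rose and 48 that fell among 314 (91 adjusted over the list alone; adjusted p = 0.320), with rises at Birc3, which encodes an inhibitor of apoptosis (1.97 ± 0.14), and Traf1, which encodes an adaptor of TNF receptor signalling (1.17 ± 0.11). Interferon-stimulated genes had 4 that rose and 10 that fell among 130 (7 adjusted over the list alone; adjusted p = 0.399), with falls at Ifih1, an RNA sensor gene (-0.73 ± 0.12), and Usp18 (-1.77 ± 0.31). Replicate 1 of WT vehicle and of WT Dex stood above the other libraries of its group on this list, by 0.38 and 0.47 log2 units. Without WT Dex replicate 1, these 2 lists passed as lower with Dex, at adjusted p = 0.0210 for NF-kB targets (0.0210 to 0.684 over its camera alternatives) and 0.00631 for interferon-stimulated genes (0.00631 to 0.842). That fit keeps WT vehicle replicate 1, which also stands high on both lists, among the controls. Neither list passed without the 3 WT libraries numbered 1. Antigen presentation had 9 that rose and 11 that fell among 111 (20 adjusted over the list alone), with a mean of -0.02, a median of 0.05 and a test direction of up. Ctss rose by 0.54 ± 0.08 and Ciita changed by -0.94 ± 0.16. Lipid metabolism had 20 that rose and 30 that fell among 242 (56 adjusted over the list alone), with Acadl, a fatty acid oxidation gene, at 1.80 ± 0.21 and Fabp5 at -1.61 ± 0.21. Macrophage lineage genes had 53 that rose and 33 that fell among 351 (95 adjusted over the list alone), with a mean of -0.02, a median of 0.03 and a test direction of up. Cx3cr1, the fractalkine receptor gene, fell from 23.1 ± 3.2 to 9.45 ± 0.28 CPM. Coactivators and corepressors had 22 that rose and 9 that fell among 202 (30 adjusted over the list alone), with Ncoa1 at 1.09 ± 0.12, and cell cycle genes 21 and 10 among 150 (32 adjusted over the list alone), with Cdkn2c at 1.07 ± 0.13.

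Markers of other cells did not pass with Dex either, with adjusted p from 0.193 for B cells to 0.985 for T and NK cells. Peaks that rose and fell numbered 3 and 3 among 73 for neutrophils, 4 and 12 among 113 for dendritic cells, 1 and 5 among 37 for B cells, and 6 and 3 among 69 for T and NK cells. They numbered 3 and 5 among 49 for fibroblasts and stroma, 1 and 4 among 45 for mast cells and basophils, and 4 and 2 among 34 for erythroid cells and megakaryocytes. The T and NK list had a mean of -0.05 and a median of 0.01, and the erythroid list a mean of -0.01 with a test direction of up.

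In all, 11137 peaks rose and 10518 fell with Dex in WT, which is 16.6% of the tested peaks. Of these, 1734 rose and 2721 fell at least 2-fold. Peaks that fell lay within 1 kb of a TSS in 4.52% of cases against 13.01% of the other peaks (odds ratio 0.317, Fisher's exact test, adjusted p = 2.71e-160). Peaks that rose did so in 11.7% against 12.3% (odds ratio 0.940, adjusted p = 0.0553), and those that rose at least 2-fold in 3.06% (odds ratio 0.223, adjusted p = 3.26e-37). Scaled by total counts alone, 8586 peaks rose and 12807 fell.

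**Figure D2:**
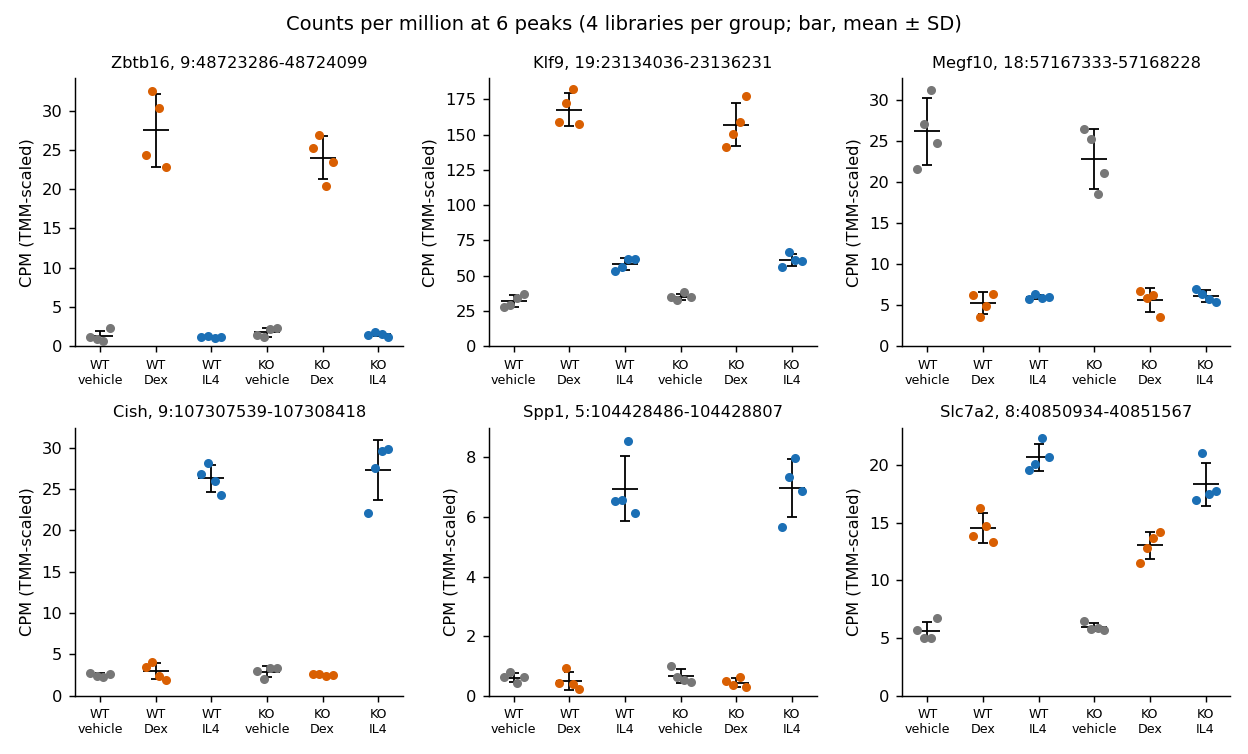
CPM in each library at peaks of Zbtb16, Klf9, Megf10, Cish, Spp1 and Slc7a2, with bars for the mean ± SD of the 4 libraries of a group. Zbtb16 lies at 27.5 CPM in WT Dex and 1.24 in WT vehicle, and Cish at 26.3 CPM in WT IL4 and 2.51 in WT vehicle.

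The effect of IL4 was asked in the same way, with the 4 WT IL4 libraries. A peak near Cish, which encodes an inhibitor of cytokine signalling, at chromosome 9, 107307539 to 107308418, rose from 2.51 ± 0.25 to 26.3 ± 1.6 CPM (SD, n = 4), a log2 fold change of 3.38 ± 0.14 (SE). Itgax, which encodes the integrin CD11c, rose at a peak 7.7 kb away from 2.01 ± 0.35 to 21.02 ± 2.51 CPM. Spp1 rose at a peak 6.5 kb away by a log2 fold change of 3.48 ± 0.23. The largest rise was at a peak 326 kb from Mir3961 (chromosome 13, 83023869 to 83024711), from 0.264 ± 0.25 to 9.98 ± 0.49 CPM (5.30 ± 0.27). Accessibility fell at a peak 54.6 kb from Ifng, the interferon gamma gene, from 8.35 ± 1.8 to 1.51 ± 0.68 CPM. It also fell at a peak 0.4 kb from the TSS of Nfkbiz, a gene of the NF-kB list, from 52.7 ± 5.3 to 27.7 ± 1.3 CPM. The other largest rises were assigned to Tex9 (4.41 ± 0.22, SE), Dut (4.30 ± 0.20), Kcnd3os (4.28 ± 0.23), Nbas (4.10 ± 0.19) and Vwf (4.02 ± 0.22). The other largest falls were assigned to Rapgef5 (-2.57 ± 0.37), Gtdc1 (-2.51 ± 0.40) and Urah (-2.50 ± 0.24).

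IL4 and STAT6 targets had 189 peaks that rose and 30 that fell among 400 with IL4, with 234 called when adjusted over the list alone. Of its 34 genes, 32 had a peak that rose, and the mean log2 fold change was 0.54 (camera, adjusted p = 8.51e-09; adjusted p = 0.00210 with an estimated correlation, and from 1.78e-12 to 0.00435 over its camera alternatives). The other lists did not pass in the reported fit, although many of their peaks were called. Of all tested peaks 35.4% were called with IL4, so calls within a list do not by themselves set it apart. With peaks within 10 kb of a TSS 3 lists passed, the added ones being inflammatory cytokines and NF-kB targets and cell cycle genes, both lower with IL4. That setting compared the list peaks near a TSS with all other tested peaks. Peaks within 1 kb of a TSS tended to fall with IL4 (median log2 fold change -0.21, against 0.03 for other peaks with a TSS). The added calls therefore cannot be told apart from that shift. With loess offsets 2 lists passed, the added one being lipid metabolism, higher with IL4. The lipid list (higher) and the NF-kB list (lower) both passed with a block for the replicate number (camera, adjusted p = 0.0319 for each). They also passed without WT vehicle replicate 3 (adjusted p = 0.0486 for each), WT vehicle replicate 4 (0.0395) or WT IL4 replicate 1 (0.0267). Their adjusted p ran over the camera alternatives from 0.0173 to 0.999 and from 0.000916 to 0.650. Lipid metabolism had 79 that rose and 35 that fell among 242 (123 adjusted over the list alone; adjusted p = 0.0652), with Cpt1a, which encodes the carnitine palmitoyltransferase of fatty acid oxidation, at 2.78 ± 0.21 and Fabp5 at -1.14 ± 0.09. Tissue repair and matrix genes had 87 that rose and 41 that fell among 271 (136 adjusted over the list alone; adjusted p = 0.179), with a rise at Pdgfc of 2.71 ± 0.18. Efferocytosis and scavenger receptors had 94 and 44 among 355 (143 adjusted over the list alone; adjusted p = 0.283), with rises at the lipid scavenger receptor genes Cd36 (1.47 ± 0.13) and Scarb1 (1.35 ± 0.13). Inflammatory cytokines and NF-kB targets had 59 that rose and 96 that fell among 314 (159 adjusted over the list alone; adjusted p = 0.0652), with a rise of 2.85 ± 0.21 at a peak assigned to Nfkb1. Glucocorticoid receptor targets had 77 and 67 among 376 (145 adjusted over the list alone), with a mean of 0.07, a median of -0.02 and a test direction of down (adjusted p = 0.961). Per2, a clock gene, rose by 1.33 ± 0.12 and Klf9 by 0.87 ± 0.08.

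Interferon-stimulated genes had 16 peaks that rose and 13 that fell among 130 with IL4 (25 adjusted over the list alone), with Mx1 at 2.00 ± 0.18. Replicate 1 of WT IL4 stood 0.39 log2 units above the other 3 libraries on this list. Antigen presentation had 29 and 15 among 111 (45 adjusted over the list alone), with H2-DMb1 at -1.17 ± 0.16 and H2-DMb2 at 0.53 ± 0.07. Macrophage lineage genes had 81 and 76 among 351 (163 adjusted over the list alone), with Runx1, a transcription factor gene of blood cells, at 2.94 ± 0.14. The KLF family had 54 and 47 among 227 (103 adjusted over the list alone), with Klf4 at 1.86 ± 0.12. Coactivators and corepressors had 32 and 34 among 202 (66 adjusted over the list alone), and cell cycle genes 23 and 37 among 150 (63 adjusted over the list alone), with the cyclin gene Ccnd1 at 2.67 ± 0.22. The mean was positive and the median negative for macrophage lineage genes (0.06 and -0.01) and cell cycle genes (0.01 and -0.04), and camera gave both as down, as it did for coactivators with a mean of 0.11 and a median of 0.01. None of the 7 marker lists passed (adjusted p from 0.224 to 0.914). Peaks that rose and fell numbered 20 and 2 among 73 for neutrophils, 29 and 15 among 113 for dendritic cells, 5 and 5 among 37 for B cells, and 10 and 13 among 69 for T and NK cells. They numbered 11 and 3 among 49 for fibroblasts, 11 and 5 among 45 for mast cells and basophils, and 11 and 4 among 34 for erythroid cells and megakaryocytes, whose mean was 0.34. The mean was positive and the median negative for neutrophils (0.23 and -0.00), B cells (0.02 and -0.04), T and NK cells (0.05 and -0.03) and fibroblasts (0.13 and -0.01).

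In all, 25116 peaks rose and 20942 fell with IL4, 35.4% of the tested peaks, and 10991 rose but 2028 fell at least 2-fold. By total counts alone 27884 rose and 16843 fell. The median log2 fold change was 0.91 among peaks that rose and -0.46 among those that fell. Peaks that fell lay within 1 kb of a TSS in 31.2% of cases against 8.47% of the others (odds ratio 4.90, 95% interval 4.71 to 5.09, Fisher's exact test). Peaks that rose did so in 3.83% and peaks that fell at least 2-fold in 4.35% (odds ratio 0.322). With loess offsets, which remove a trend with abundance, the odds ratio of the falls was 1.54.

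**Figure D3:**
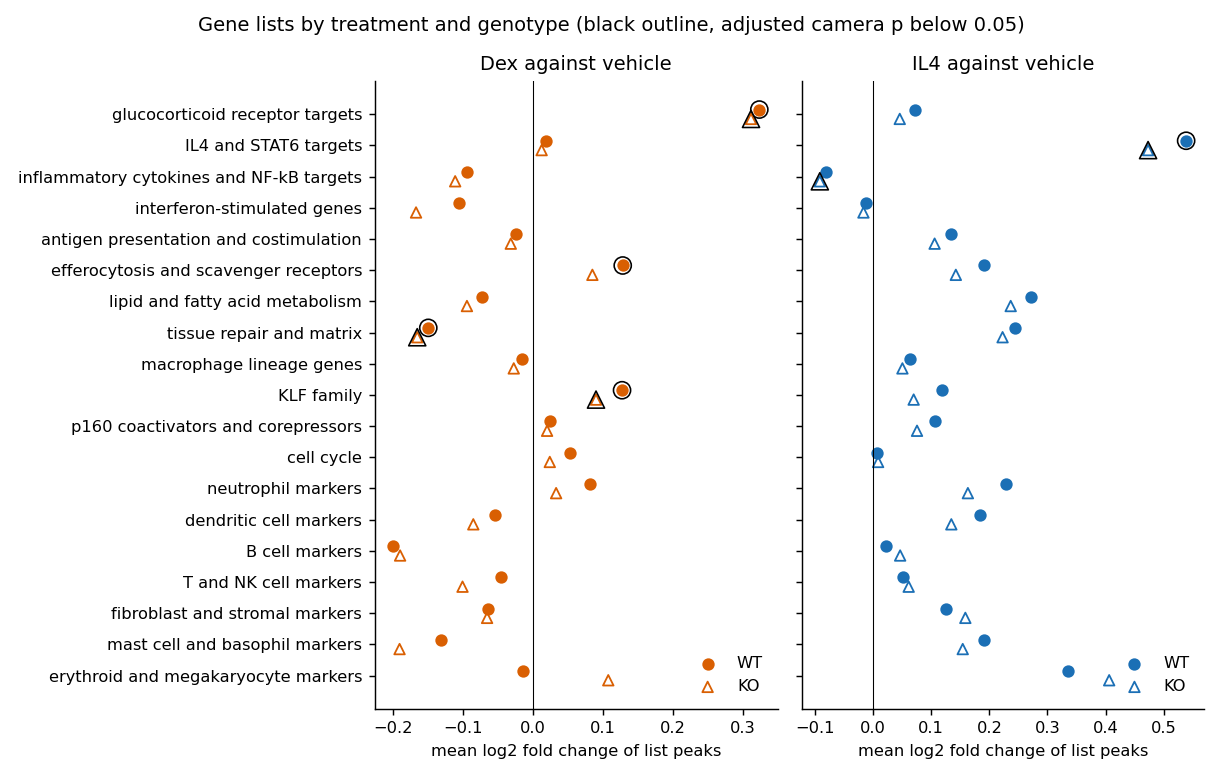
Mean log2 fold change of the peaks of each fixed list with Dex and with IL4, for WT and KO, with n = 4 libraries per group; markers with a black outline have a camera adjusted p below 0.05. Glucocorticoid receptor targets lie at 0.32 with Dex in WT, and IL4 and STAT6 targets at 0.54 with IL4.

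The direct comparison of IL4 with Dex in WT asked where the treatments differ. Fkbp5 (chromosome 17, 28515844 to 28516378) had 58.2 ± 6.9 CPM with Dex and 6.54 ± 1.3 with IL4 (SD, n = 4), and Cish 2.95 ± 0.98 with Dex and 26.3 ± 1.6 with IL4. Glucocorticoid receptor targets had 74 peaks higher with IL4 and 165 higher with Dex (252 adjusted over the list alone; mean -0.25; camera, adjusted p = 0.000225; adjusted p = 0.0177 with an estimated correlation). IL4 and STAT6 targets had 181 higher with IL4 and 60 higher with Dex (246 adjusted over the list alone; mean 0.52; adjusted p = 7.42e-05; adjusted p = 0.0177 with an estimated correlation). Tissue repair and matrix genes had 118 and 47 (169 adjusted over the list alone; mean 0.39; adjusted p = 0.00536; adjusted p = 0.0255 with an estimated correlation, and from 0.000956 to 0.245 over its camera alternatives). Lipid metabolism had 94 and 41 (139 adjusted over the list alone; mean 0.34; adjusted p = 0.0272), but adjusted p = 0.139 with an estimated correlation, 0.0519 without WT IL4 replicate 4, and from 0.00361 to 0.901 over its camera alternatives. In all, 30400 peaks were higher with IL4 and 28216 with Dex, 14871 and 2826 of them at least 2-fold. Scaled by total counts alone, which moves the median of all peaks by 0.11, the numbers were 35894 and 20279.

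Whether the same peaks changed with both treatments was asked from the overlap. An unassigned peak inside Trpm3 (chromosome 19, 22978498 to 22979786) rose by 1.88 ± 0.14 with Dex and by 1.82 ± 0.14 with IL4 (log2, SE, n = 4). Peaks assigned to Akirin1 rose by 1.27 ± 0.09 and 1.23 ± 0.09 and to Cartpt by 1.59 ± 0.13 and 1.87 ± 0.13. Slc7a2, the arginine transporter gene, rose by 1.34 ± 0.12 with Dex and 1.87 ± 0.11 with IL4, and 4831407H17Rik by 1.39 ± 0.08 and 1.04 ± 0.08. Megf10, which encodes an engulfment receptor, had 26.2 ± 4.1 CPM with vehicle, 5.23 ± 1.3 with Dex and 5.99 ± 0.28 with IL4. Peaks assigned to Nap1l2 (-2.40 ± 0.18 and -2.26 ± 0.17), 4930552P12Rik (-1.49 ± 0.10 and -1.28 ± 0.10) and Atp8a1 (-1.19 ± 0.12 and -1.34 ± 0.12) and a peak without a gene at chromosome 17, 35218541 to 35220353 (-0.75 ± 0.07 and -0.95 ± 0.07) also fell with both. In all, 2697 peaks rose with both, where independent lists of these sizes would share 2150, and 3439 fell with both, where they would share 1693. Another 1788 rose with Dex and fell with IL4 (expected 1793), and 2282 did the reverse (expected 2030). Both comparisons use the same vehicle libraries, which alone correlates the fold changes: the correlation across peaks, which are not independent replicates, was 0.107 and the covariance 0.0302. Simulated data without effects were fitted with limma on the WT libraries alone, where the observed correlation was 0.0986 against a simulated mean of 0.520, and the covariance 0.0242 against 0.0264. With the vehicle libraries split between the comparisons, 1227 to 1347 peaks rose with both (expected 1027 to 1129), 1465 to 1751 fell with both (expected 685 to 842), and the correlation ran from -0.0346 to 0.0161. In these splits 1158 to 1649 peaks fell with Dex and rose with IL4 (expected 850 to 1119), above expectation in each split. The reverse held for 750 to 1110 (expected 782 to 899), above expectation in all but 1 split. WT Dex and KO IL4, which share no library, had 2234 shared rises (expected 1897), 2654 shared falls (expected 1464) and a correlation of -0.00422. Opposite calls of that pair also exceeded expectation. In 1754 peaks Dex gave a rise and IL4 a fall (expected 1550.5), and 2371 did the reverse (expected 1791.5). Without shared libraries the excess was thus not limited to changes in the same direction.

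The responses were also measured in KO cells. With Dex, the Zbtb16 peak rose in KO from 1.75 ± 0.59 to 24.0 ± 2.8 CPM, the Fkbp5 peak at 28515844 from 5.54 ± 0.89 to 54.2 ± 4.4, and the Klf9 peak from 35.0004 ± 2.279 to 157 ± 15 (SD, n = 4). Glucocorticoid receptor targets had 111 peaks that rose and 19 that fell (159 adjusted over the list alone; mean 0.31; camera, adjusted p = 1.50e-11; adjusted p = 0.000103 with an estimated correlation). Tissue repair and matrix genes had 14 that rose and 36 that fell (52 adjusted over the list alone), at adjusted p = 0.0287. That call was lost with an estimated correlation (adjusted p = 0.0854) and without KO vehicle replicate 1 (0.0734), KO Dex replicate 2 (0.0535) or KO Dex replicate 4 (0.0512), over a range from 0.00761 to 0.121 among the camera alternatives. The KLF family had 42 and 17 (75 adjusted over the list alone), at adjusted p = 0.0358, and adjusted p = 0.146 with an estimated correlation. Without KO Dex replicate 3 or 4 it was 0.0814 or 0.0683, over a range from 7.34e-05 to 0.153. Efferocytosis and scavenger receptors had 63 and 24 (103 adjusted over the list alone; adjusted p = 0.0630). They passed without KO vehicle replicate 2 (0.0411) or KO Dex replicate 1 (0.0248), over a range from 0.00179 to 0.239, and B cell markers without KO vehicle replicate 4 (0.0289, range 0.0289 to 0.154). In all, 9071 peaks rose and 8623 fell with Dex in KO, and by total counts alone 6921 and 10833. Of the peaks called in WT, 6471 that rose and 5599 that fell were also called in that direction in KO, and 1 was called in opposite directions.

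With IL4, the Cish peak rose in KO from 2.92 ± 0.65 to 27.3 ± 3.6 CPM and the Itgax peak from 2.74 ± 0.55 to 19.1 ± 2.9 (SD, n = 4). The Tex9 peak reached 7.23 ± 2.3 CPM in KO IL4 and 15.2 ± 1.1 in WT IL4. IL4 and STAT6 targets had 166 peaks that rose and 23 that fell (201 adjusted over the list alone; mean 0.47; camera, adjusted p = 6.66e-09; adjusted p = 0.00197 with an estimated correlation). Inflammatory cytokines and NF-kB targets had 48 that rose and 94 that fell (148 adjusted over the list alone; mean -0.09; adjusted p = 0.0256), but adjusted p = 0.545 with an estimated correlation and 0.0517 without KO vehicle replicate 1, over a range from 0.000877 to 0.545. Lipid metabolism (adjusted p = 0.0517) passed as higher without KO vehicle replicate 3 (0.0393), KO IL4 replicate 2 (0.0410), KO IL4 replicate 4 (0.0352) or the 3 WT libraries numbered 1 (0.0497), over a range from 0.0286 to 0.639. Erythroid and megakaryocyte markers passed without KO vehicle replicate 3 (0.0322) or KO IL4 replicate 4 (0.0387), over a range from 0.0322 to 0.639. In all, 22160 peaks rose and 18113 fell with IL4 in KO, and by total counts alone 24042 and 14808. Peaks that fell lay within 1 kb of a TSS in 30.0% of cases (odds ratio 4.22, Fisher's exact test), and those that fell at least 2-fold in 3.30% (odds ratio 0.242). Of the peaks called in WT, 18597 that rose and 13452 that fell were also called in that direction in KO, and 1 and 2 were called in opposite directions. Whether an effect differs between the genotypes is tested by the interactions.

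The genotypes were compared under each treatment, beginning with Ncoa2, the targeted gene. Ncoa2 has 21 tested peaks, 17 inside the gene and 4 upstream. The promoter peak (chromosome 1, 13372246 to 13374626) had 86.1 ± 1.9 CPM in WT vehicle and 87.6 ± 4.2 in KO vehicle (SD, n = 4). The log2 difference was 0.02 ± 0.06 (SE; adjusted p = 0.945), with -0.03 ± 0.06 under Dex (0.01 by total counts and 0.04 with loess offsets) and 0.05 ± 0.06 under IL4. A peak inside the gene at 13256160 to 13256636 was lower in KO, at 3.09 ± 0.35 against 6.89 ± 0.63 CPM in vehicle (-1.15 ± 0.16), and by -1.04 ± 0.14 with Dex and -1.32 ± 0.15 with IL4. A peak 49.7 kb upstream at 13423543 to 13423943 was higher in KO, by 2.96 ± 0.21, 2.43 ± 0.15 and 2.60 ± 0.22. In all, 1 peak was higher and 1 lower in KO with vehicle, 1 and 2 with Dex, and 1 and 4 with IL4. The peak at 13342449 to 13343216 was lower with Dex (-0.62 ± 0.15) and IL4 (-0.80 ± 0.15), the Dex call being lost without KO Dex replicate 4 (adjusted p = 0.0826, range 0.00587 to 0.0826). With IL4 the peak at 13295540 to 13295827 was also lower (-0.73 ± 0.17), a call lost with DESeq2 (0.0509) and without WT IL4 replicate 2 (0.0677) or KO IL4 replicate 1 (0.0561), over a range from 0.00142 to 0.0677. So was the peak at 13267226 to 13267787 (-0.52 ± 0.14), which kept its call in 6 of 18 alternatives, over a range from 0.0287 to 0.249. It was lost without WT IL4 replicates 2, 3 or 4 (0.249, 0.0950 and 0.0726) or KO IL4 replicates 1 to 4 (0.0561, 0.0978, 0.152 and 0.126). The labels do not say which part of the gene is deleted, so these peaks check nothing about the deletion. With Dex in WT, 5 of the 21 peaks rose and no other was called, with 1.26 ± 0.19 at 13311600 to 13312261. The call at 13366184 to 13366859 was lost with DESeq2 (adjusted p = 0.0749) and by total counts (0.0508). It was also lost without replicate 1 of WT vehicle (adjusted p = 0.132) or WT Dex (0.0524), replicate 4 of WT vehicle (0.0805) or WT Dex (0.0734), or the 3 WT libraries numbered 1 (0.200), over a range from 0.0157 to 0.200. With IL4, 3 rose and 2 fell, with 1.59 ± 0.24 at 13299665 to 13299973 and -0.21 ± 0.06 at the promoter peak. The promoter value was 0.07 with loess offsets, and the other fall, at 13424425 to 13424947, was lost without WT IL4 replicate 3 (adjusted p = 0.0563) or 4 (0.0849), over a range from 0.00502 to 0.0849.

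Away from Ncoa2, the smallest p-values came largely from chromosome 9. A peak near Scn10a, a sodium channel gene, at chromosome 9, 119736924 to 119737536, had 29.6 ± 3.7 CPM in WT vehicle and 1.38 ± 0.47 in KO vehicle. The log2 differences were -4.46 ± 0.15, -4.45 ± 0.14 and -4.23 ± 0.15 (SE, n = 4) under vehicle, Dex and IL4. A peak inside Tgfbr2, which encodes a receptor of TGF beta, at chromosome 9, 116156573 to 116157166, was higher in KO by 2.65 ± 0.13, 3.20 ± 0.14 and 2.79 ± 0.14. Higher peaks in KO were also assigned to Myrip (3.98 ± 0.15 in vehicle), 1700020M21Rik (2.73 ± 0.11), Rec114 (2.43 ± 0.12) and, on chromosome 15, Tmem74 (4.34 ± 0.21). Lower peaks were assigned to 1700017B05Rik (-3.37 ± 0.15), 4930509E16Rik (-4.81 ± 0.26), Pstpip1 (-3.21 ± 0.18) and 4930563M21Rik (-4.32 ± 0.25) in vehicle, to Mns1 with Dex (-3.32 ± 0.17) and IL4 (-3.03 ± 0.17), and to Mir467h with IL4 (-3.60 ± 0.18). In all, 396 peaks were higher and 406 lower in KO with vehicle, 567 and 673 with Dex, and 615 and 479 with IL4. By total counts alone the numbers were 433 and 336, 651 and 537, and 626 and 427. Together 1968 peaks were called at least once, 441 of them in all 3 comparisons, each with the same sign.

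The called peaks lay close together. Of the 1968, 921 (46.8%) fell in 24 dense windows of 5 Mb on 10 chromosomes, which hold 4.24% of the tested peaks; the highest share in 1000 shuffles was 0.711%. On chromosome 9 the dense windows ran from 50 to 75 Mb and from 115 to 125 Mb, and on chromosome 1 from 5 to 20 Mb, which holds Ncoa2, and from 120 to 130 Mb. Near the end of the X chromosome, the window from 165 to 170 Mb had 128 of 219 tested peaks called (58.4%), and the window from 90 Mb on Y 15 of 21 (71.4%). Outside the windows 1047 peaks were called, 248 with vehicle, 572 with Dex and 446 with IL4.

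**Figure D4:**
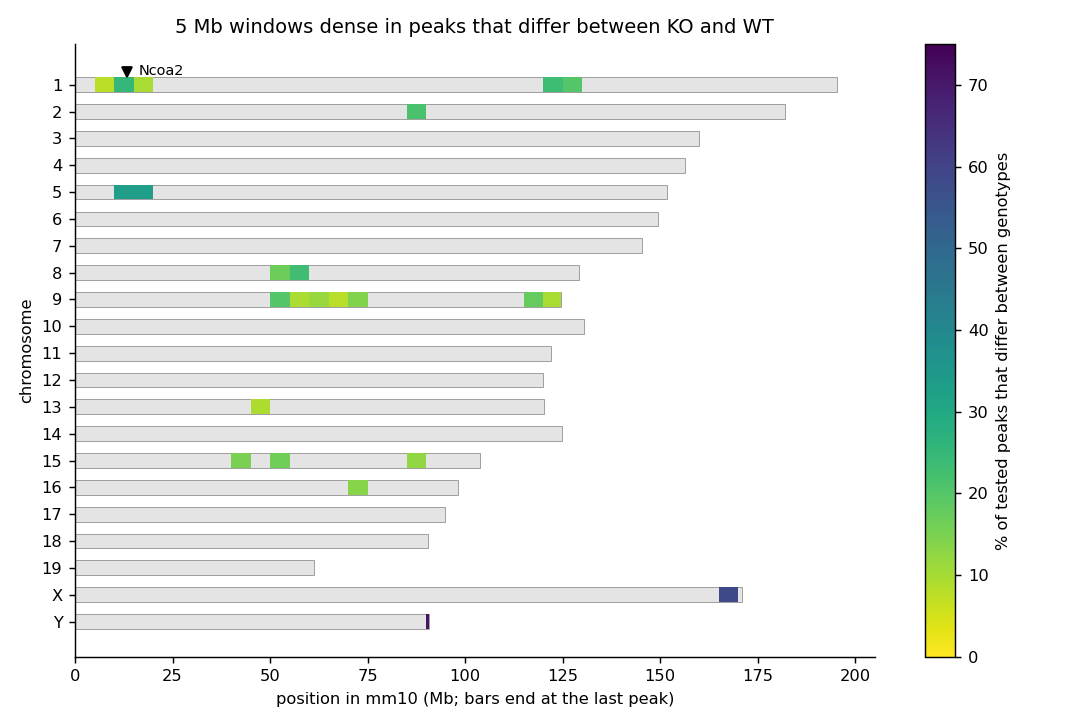
Chromosomes drawn to scale in Mb up to their last peak, with the 24 dense windows of 5 Mb coloured by the percentage of tested peaks called between KO and WT in any of 3 treatments (n = 4 libraries per group). Windows on 10 chromosomes hold 46.8% of the called peaks.

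The fixed lists gave 3 calls between genotypes, each lost without some libraries. With Dex, interferon-stimulated genes were lower in KO (mean -0.18; camera, adjusted p = 0.0179; adjusted p = 0.771 with an estimated correlation), with none of its 130 peaks called, also when adjusted over the list alone. The groups had mean log2 CPM of 1.89 ± 0.24 in WT Dex and 1.78 ± 0.02 in KO Dex (SD, n = 4). The call was lost without WT Dex replicate 1 (adjusted p = 0.868), KO Dex replicate 3 (0.0613), KO Dex replicate 4 (0.145) or the 3 WT libraries numbered 1 (0.857), over a range from 0.00198 to 0.868. Neutrophil markers were higher in KO with vehicle (mean 0.23; adjusted p = 0.0163; adjusted p = 0.898 with an estimated correlation) and with Dex (mean 0.18; adjusted p = 0.0179; adjusted p = 0.505 with an estimated correlation). None of its 73 peaks was called in either, also when adjusted over the list alone. The vehicle call was lost without KO vehicle replicate 3 (0.166) or 4 (0.536), over a range from 0.000295 to 0.999. The Dex call was lost without WT Dex replicate 3 (0.0534), KO Dex replicate 3 (0.0699), KO Dex replicate 4 (0.147) or the 3 WT libraries numbered 1 (0.0611), over a range from 0.00192 to 0.677. With IL4 no list passed in the reported fit (smallest adjusted p = 0.172, for interferon-stimulated genes). Interferon-stimulated genes passed as lower in KO with IL4 without WT IL4 replicate 2 (0.0446), 3 (0.00661) or 4 (0.0133), over a range from 0.00661 to 0.956. With vehicle (0.0946) they did so without WT vehicle replicate 3 (0.00455) or 4 (0.0221), over a range from 0.00455 to 1.00.

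**Figure D5:**
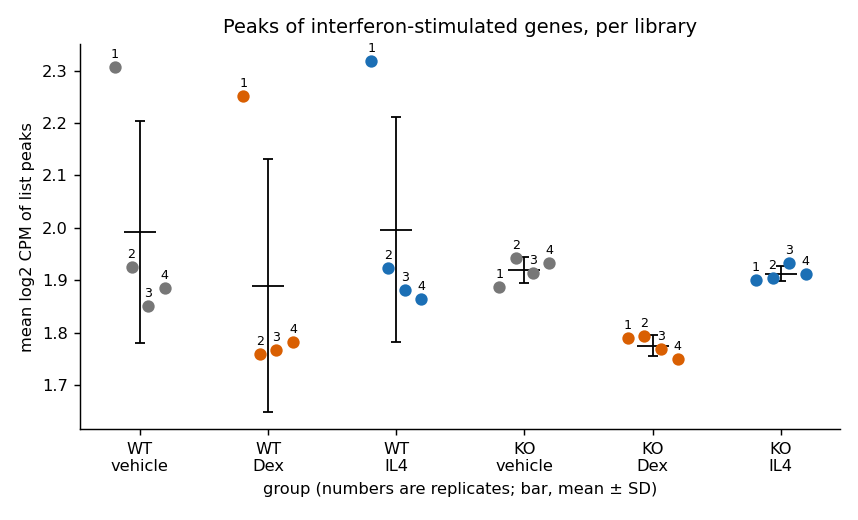
Mean log2 CPM of 130 peaks of interferon-stimulated genes in each library, by group, with the number of the replicate and bars for the group mean ± SD. Replicate 1 is the highest library in each WT group, 0.38, 0.47 and 0.39 log2 units above the next, and KO Dex libraries lie at 1.78 ± 0.02 (SD, n = 4).

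Whether the treatment effects differ between genotypes was tested by the interactions. For Dex, edgeR called 0 of 130103 peaks, with a smallest adjusted p of 0.830, and DESeq2 also called 0. In edgeR 4498 peaks (3.46%) had an unadjusted p below 0.05, fewer than chance alone gives at that threshold. For IL4, 3 peaks were called. The number was 6 without the 3 WT libraries numbered 1, 5 without WT IL4 replicate 1, and 1 without KO vehicle replicate 1 or KO IL4 replicate 1, and ran from 1 to 9 over all alternatives (from 0 to 1 for Dex). A peak without a gene at chromosome 9, 63927777 to 63928824, went from 3.60 ± 0.41 to 10.5 ± 1.6 CPM in KO and from 3.16 ± 0.46 to 2.87 ± 0.62 in WT (SD, n = 4; log2 difference 1.75 ± 0.25, SE, edgeR adjusted p = 8.48e-05). A peak inside Ldlrad4, which encodes a membrane regulator of TGF beta signalling, at chromosome 18, 68058969 to 68059785, went from 15.2 ± 2.1 to 13.8 ± 2.1 CPM in KO and from 11.3 ± 1.1 to 18.2 ± 2.2 in WT (-0.84 ± 0.15, adjusted p = 0.0118). The peak assigned to 1700020M21Rik, also on chromosome 9, had -0.80 ± 0.15 (adjusted p = 0.0232). Both peaks on chromosome 9 lie in dense windows. The Ldlrad4 call was lost without replicate 1 of WT vehicle (adjusted p = 0.103), KO vehicle (0.10004) or KO IL4 (0.0758), WT IL4 replicate 2 (0.121) or KO IL4 replicate 4 (0.0799), over a range from 0.000129 to 0.121. The 1700020M21Rik call was lost with DESeq2 (0.0608) and without any of 7 libraries, which were replicates 2 and 3 of WT vehicle (0.312 and 0.212), 4 of WT IL4 (0.127), 1 and 4 of KO vehicle (0.0535 and 0.0852), and 1 and 3 of KO IL4 (0.0758 and 0.0505), over a range from 0.00100 to 0.312. No fixed list passed in either interaction (smallest adjusted p 0.957 for Dex and 0.995 for IL4).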

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

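The dense windows and the peaks chosen on the mean genotype difference were tested only after the result was seen, while the other tests below were written before.

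In 365 groups of 4 libraries, the gap of the highest or the lowest library to its neighbour was compared with the whole range of its group, and chance picks out about 1 group in 20. Among 114 group means of the gene lists 12 libraries stood apart, where chance gives 5.7, and among 239 groups of named peaks 19 did, where chance gives 11.95. Each value below is the gap as a share of the range. In total counts, WT vehicle replicate 1 stood high (0.859).

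Among the lists, interferon-stimulated genes stood high in replicate 1 of WT vehicle (0.836), WT Dex (0.954) and WT IL4 (0.872), and inflammatory cytokines and NF-kB targets in WT IL4 replicate 1 (0.981). Glucocorticoid receptor targets were low in WT IL4 replicate 3 (0.899) and efferocytosis receptors in WT vehicle replicate 2 (0.833). Antigen presentation was high in WT IL4 replicate 2 (0.880), and lipid metabolism (0.852) and tissue repair (0.869) in WT vehicle replicate 4. Mast cell and basophil markers were low in replicate 2 of WT vehicle (0.904) and WT Dex (0.885), and high in KO Dex replicate 1 (0.859).

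Among the named peaks of the treatments, Ppp1r21 was low in WT vehicle replicate 3 (0.874), Ifih1 in WT vehicle replicate 4 (0.853) and 4930552P12Rik in WT vehicle replicate 4 (0.908). Tlk1 was high in WT Dex replicate 1 (0.857) and Ctss in WT Dex replicate 2 (0.903). With IL4 in WT, Mir3961 (0.910) and H2-DMb2 (0.839) were high in replicate 2, and Kcnd3os (0.874) and Spp1 (0.831) in replicate 3, and Kcnd3os also in WT vehicle replicate 4 (0.845). Among the peaks of the genotype comparisons, Tgfbr2 was high in WT vehicle replicate 3 (0.955) and low in KO Dex replicate 1 (0.878). Pstpip1 was high in KO vehicle replicate 4 (0.867), Tmem74 in WT Dex replicate 1 (0.940), Rec114 in WT IL4 replicate 1 (0.901) and 4930509E16Rik in KO IL4 replicate 2 (0.842). For Ncoa2, the peak at 13328443 was high in WT vehicle replicate 1 (0.907), that at 13256160 in KO Dex replicate 4 (0.833) and that at 13342449 in KO IL4 replicate 2 (0.843).

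The IL4 effect differed between the genotypes, by the interaction test, at the peak without a gene on chromosome 9 (log2 difference 1.75), at Ldlrad4 (-0.84) and at 1700020M21Rik (-0.80). Among 60 reassignments of genotype within treatment, 5 called at least as many peaks as the real one, which called 5, and the highest other called 420. For Dex edgeR called 0 in the reported fit, with 4498 at an unadjusted p below 0.05, fewer than chance alone gives, and DESeq2 called 0. Among the reassignments for Dex the real one called 0, which all 60 must reach, and the highest other called 959. Such counts point to a structure of the samples: reassigning genotype separately in each treatment turns the difference between genotypes into an interaction. These splits therefore say nothing about chance.

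For each of the 8 comparisons of pairs of groups, only 1 of 35 splits of the 8 libraries, the real one, called as many peaks. No smaller share is possible with 35 splits, and every other split mixes libraries of both groups. The labels also do not say whether libraries came from separate mice or cultures. The splits thus argue against a random division of these libraries, but they do not exclude chance. Fitted on those 8 libraries, the real split and the highest other called 19263 and 92 peaks for Dex in WT, 45747 and 1 for IL4 in WT, and 56338 and 0 for IL4 against Dex. In KO they called 17449 and 102 for Dex and 38562 and 1 for IL4, and between genotypes 780 and 48 with vehicle, 1082 and 10 with Dex, and 1337 and 25 with IL4.

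Peaks that differ between genotypes lie in segments: the dense windows held 46.8% of them, and the highest of 1000 shuffles 0.711%. DNA of another strain, carried along with the genotype, is a candidate explanation that gives such segments, and the window around Ncoa2 is among them, but no sequence was examined here. Among called peaks in the windows, the share with an interaction p below 0.05 exceeded that of all tested peaks by 13.6 percentage points, past the 10 set for a difference that depends on the treatment. Calls in any of 3 treatments favour such peaks, and among peaks chosen on the mean difference the excess was 7.39, with 14.3% against 6.90% of tested peaks, so treatment dependence stays open. Outside the windows 270 peaks were called between the vehicle groups against 47 in the highest other split, but the windows were drawn from the same calls, so smaller segments and an effect of GRIP1 loss both stay open there.

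Falls with IL4 are mostly small and enriched at promoters, where 31.2% of them lie against 8.47% of other peaks, and 79.1% of 13625 promoter peaks had a log2 fold change below 0, with a median of -0.21 (-0.17 in KO, and 0.07 with Dex in WT). Unequal depth is argued against by an odds ratio of 4.91 (95% interval 4.71 to 5.11) after the libraries were thinned to the lowest total among them. A scaling error that depends on abundance cannot be told apart from a real shift: loess offsets gave 1.54 (1.47 to 1.61), and such offsets would also remove a real shift that follows abundance. A small fall shared by most promoters may thus be an effect of IL4 or of scaling, and the labels name no spiked control to decide.

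Interferon-stimulated genes stand high in replicate 1 of each WT group, by 0.38, 0.47 and 0.39 log2 units over the next library. Depth is argued against, since the smallest gap after thinning was 0.365. Cells of another kind are argued against, as 0 of the 7 marker lists stood above the other libraries in all 3 groups by 0.25 of that gap. KO cells in these libraries are argued against by the KO groups themselves, which were not high on this list. Their means were 1.92, 1.78 and 1.91 log2 CPM with vehicle, Dex and IL4, against 2.31, 2.25 and 2.32 in WT replicate 1. The largest position was 0.198 on a scale from 0 at the WT mean to 1 at the KO mean over 3282 peaks. That position argues only against libraries made mostly of KO cells. No biological explanation was tested, and the labels give no batch.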

How the results depend on the processing

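The authors' mark, the fit without the 3 WT libraries numbered 1, and the lists with a library left out were chosen only after the data were seen. For peak counts, alternatives gave these ratios to the reported ones: DESeq2 0.634 to 0.874, DESeq2 size factors 0.986 to 1.01, total counts 0.958 to 1.00, loess offsets 0.903 to 1.00, no low-count filter 0.981 to 1.04, and 1 CPM filter 0.976 to 1.00. Others were only the groups compared 0.873 to 1.22, the authors' mark 0.659 to 0.779, without the 3 WT libraries numbered 1 0.808 to 1.07, and leaving out a library 0.729 to 1.08. A count does not say which peaks.

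At an adjusted p below 0.01 the counts were 13050 for WT Dex, 10308 for KO Dex, 734 and 703 for KO against WT with Dex and IL4, and 1 for the IL4 interaction. At least 2-fold gave 4455 for WT Dex, 13019 for WT IL4, 17697 for IL4 against Dex, 3499 for KO Dex, 10649 for KO IL4, 423, 526 and 595 for KO against WT with vehicle, Dex and IL4, 1 for the IL4 interaction and 851 for both treatments. Both thresholds lower counts by construction. The authors' mark, which leaves fewer peaks, gave 38926 for IL4 against Dex and 721 for KO against WT with IL4, and DESeq2 gave 786 for KO against WT with Dex. The IL4 interaction called 5 with only the groups compared, 6 without the 3 WT libraries numbered 1, and 1 to 5 with a library left out: 1 without KO vehicle replicate 1 or KO IL4 replicate 1, and 5 without WT IL4 replicate 1. With vehicle libraries split, both treatments shared 3041, 3004, 2950, 3058, 2755 and 2692 peaks, where each comparison has fewer libraries.

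Blocking for the replicate number gave ratios of 1.06 to 1.35, and called 1 peak for the Dex interaction and 9 for the IL4 interaction. Correlations between libraries were taken after the mean of the group was subtracted at each peak. Libraries of a number then correlated best with each other in 4 of 4 cases for Dex, IL4 and IL4 against Dex in WT and for IL4 in KO. For Dex in KO it was 3 of 4. These correlations ran from 0.00337 to 0.202, and between genotypes 0 of 4 matched. Libraries of a number within a genotype may thus share an origin, which the labels do not give and the reported fit ignores.

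The lists that passed numbered 4 for WT Dex, 1 for WT IL4, 4 for IL4 against Dex, 3 for KO Dex, 2 for KO IL4, and 1, 2 and 0 for KO against WT with vehicle, Dex and IL4. With an estimated correlation WT Dex, KO Dex and KO IL4 had 1 each, and KO against WT 0 with vehicle and 0 with Dex. That setting without the 3 WT libraries numbered 1 gave 1, 1 and 1, 2 for IL4 against Dex, and 0 and 0; without them at the preset correlation KO against WT with Dex had 0. The fry test gave 7 for WT Dex, 14 for WT IL4, 13 for IL4 against Dex, 9 for KO Dex, 11 for KO IL4, and 0 and 0 for KO against WT with vehicle and Dex. The block gave 3 for WT IL4 and 4 for KO IL4, peaks within 10 kb gave 3, 5 and, for KO against WT with vehicle, 2, and loess offsets 2 for WT IL4. Lists cut to 10 kb were compared with all other tested peaks, so with IL4 the fall of promoter peaks enters their counts. With a library left out the lists numbered 4 to 6 for WT Dex, 1 to 3 for WT IL4, 3 to 4 for IL4 against Dex, 1 to 4 for KO Dex, 1 to 4 for KO IL4, and 0 to 2, 0 to 2 and 0 to 1 for KO against WT with vehicle, Dex and IL4.

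For promoters, the odds ratio of Dex rises, reported as 0.940, was reversed at 1.04 within 3 kb (Fisher's exact test, adjusted p = 0.139). At 2-fold it was 0.223, in the same direction. The odds ratio at 2-fold of IL4 falls was 0.322 in WT and 0.242 in KO and of falls against Dex 0.349, each reversed. At the Ncoa2 promoter the IL4 effect was 0.0697 with loess offsets. There KO against WT with vehicle ran, with a library left out, from -0.000575 without KO vehicle replicate 3 to 0.0562 without KO vehicle replicate 1, and with Dex it was 0.0116 by total counts and 0.0449 with loess offsets. Of 133 results on named peaks, 123 kept direction and side in each alternative tried. Most of these peaks were named for a small p or a large fold change in the same libraries, which favours keeping a call. Where a result changed between alternatives, the cause was not tested unless stated. Motif enrichment and its alternatives were not run.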

Other observations

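The genes in the next paragraph were chosen only after the values were seen.

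Some genes gathered many peaks that changed at least 2-fold. With Dex in WT, 12 of 29 peaks assigned to the kinase gene Wnk1 rose, 11 of 31 of F13a1, which encodes a subunit of coagulation factor XIII, 11 of 28 of Fkbp5, 7 of 11 of Cd163 and 6 of 8 of Klf9. With Dex 7 of 76 peaks of Pde4d, 6 of 34 of the adhesion receptor gene Cd44 and 5 of 11 of Ocstamp fell. With IL4, 16 of 26 peaks of Fam198b, 13 of 24 of the purine receptor gene P2ry1, 12 of 36 of Cd36 and 12 of 33 of Igf1 rose. With IL4, 8 of 30 peaks of Nfkbiz, 6 of 11 of Ocstamp and 5 of 13 of Irak3 fell.

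Peaks of 1 kb or more made up 10.3% of the tested peaks, 19.5% of those that rose with Dex and 28.1% of those that fell with IL4 in WT.

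Fewer peaks were called for each treatment in KO than in WT, and a smaller response of the same peaks in KO may give this. Over peaks chosen on the mean effect of both genotypes, the KO response was 0.888 of the WT response for Dex (36563 peaks) and 0.891 for IL4 (59771 peaks), with n = 4 libraries per group. The KO response minus the WT response was -0.0631 ± 0.0447 for Dex and -0.0728 ± 0.0316 for IL4 (SE). A permutation test gave p = 0.187 for Dex and p = 0.0396 for IL4 (adjusted p = 0.0792). It reassigned genotype separately in the vehicle and the treated libraries. A genotype difference shared by both therefore enters these p-values, and they do not decide. Both ratios lie below 1, but these data leave the hypothesis open. Without the 3 WT libraries numbered 1, which leaves fewer WT libraries, the order of the counts turned, with 17491 in WT and 18978 in KO for Dex and 39903 and 41519 for IL4.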
